A study of Mus musculus with 11 samples.

How the data were processed

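Chromatin immunoprecipitation followed by sequencing was performed for 4 histone H3 methylation marks in mouse cardiomyocytes at 2 stages. Neonatal cardiomyocytes came from animals of 1 day and adult cardiomyocytes from the left ventricle of animals of 2 months, per the labels. The series holds 11 samples. Of these, 8 are immunoprecipitated libraries, 1 per mark and stage, and 3 are input libraries, among them a separate input for neonatal H3K4me3. Groups were taken from the sample titles. The labels name the left ventricle for the adult cells only, so heart region and age differ together between the stages. Per the labels' protocols, chromatin was sonicated, precipitated with 1 commercial antibody per mark and amplified by PCR before sequencing.

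Bowtie 0.12.8, SICER 1.1, MACS 1.4.2 and DiffBind 1.2.0 and the mouse genome build mm9 are named per the submitters' processing notes. All coordinates are given in mm9 as the authors deposited them, with the end base included. For each immunoprecipitated library the authors deposited a list of SICER islands, which are enriched stretches built from windows of fixed size, and a list of MACS regions. Each island carries a score that the authors' caller gave it, and the deposited MACS lists carry a score per region as MACS writes it. These scores were used only to describe, rank or filter regions within a list. The lists were called per sample. The reads of the input libraries were not analysed here on their own.

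The authors deposited 12 comparison tables made with DiffBind, 4 between the stages and 8 between mouse embryonic stem (mES) cells and each stage. Per the deposited description of the tables, they were made pairwise with default settings and hold only regions with a false discovery rate under 0.01. This rate compares the reads of 2 libraries and not the conditions. The deposited value per stage is the log2 of a normalised read count, and the fold column is the difference of those values on the log2 scale. Dividing the unlogged values by the lowest value of their column gave whole numbers for 100% of the values at a tolerance of 0.01. These whole numbers were taken as reads left after subtraction of control reads, with a floor of 1 read. The normalised counts are those reads times 1 factor per library, with factors of 1.30 and 0.771 for neonatal and adult H3K4me3, 1.41 and 0.707 for H3K79me2, 1.26 and 0.792 for H3K27me3, and 0.954 and 1.05 for H3K9me3. The mES libraries are no samples of this series, so only the fold and false discovery rate columns of their tables were used, and 8 columns of mES values were not used.

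Total sequencing depth is not given in the sources used here. The regions of the stage tables held 467818 neonatal and 1302633 adult reads for H3K4me3, 1532772 and 1909655 for H3K79me2, 495109 and 667785 for H3K27me3, and 1188973 and 671527 for H3K9me3. These sums cover listed regions only and are not library sizes. A few regions took a large part of them, as given with the comparisons.

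With 1 library per group no test across replicates was possible, and no p-value was computed. Islands and table regions on chromosomes 1 to 19, X and Y were counted. Islands were called overlapping when they shared at least 1 bp, and SICER overlaps between the stages of a mark and between marks of a stage were set beside the mean of 100 seeded shuffles that moved the islands to random places on the same chromosome. Shares within classes of islands and overlaps under alternative settings were not shuffled. Shares carry 95% Wilson intervals. Read ratios carry exact conditional binomial 95% intervals. When the lower stage stood at the floor of 1 read, the lower limit of that interval was written as a lower bound. It holds for the reads of the tables, which are left after control subtraction, and a region at the floor can still hold an island. The Wilson and binomial intervals cover counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules. Bootstrap intervals were used for the X chromosome, from 1000 resamples of blocks of 1 Mb. Median ratios in wide H3K4me3 regions carry bootstrap intervals from 1000 resamples of the regions. Both kinds of bootstrap interval cover the spread over places in the genome and not the spread between animals. The code for read ratios was tested on simulated reads for the H3K4me3 comparison of 10401 regions. It gave the right direction for 200 of 200 regions changed 4-fold, and its interval held the true fold in 193. The changed regions were drawn from those of higher signal, without control subtraction or duplicate reads. The simulation therefore did not test the bounds at the floor of 1 read.

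The comparisons, the fixed rule for named regions and most alternatives were chosen before the data were examined, and the tests of explanations in the closing observations after the results had been seen. All regions of a stage table counted as changed, because the tables hold only regions past the authors' threshold. The tables name no genes, and an annotation of mm9 was not used here, so regions are named by coordinates and the planned gene lists were not run. The named regions of a mark are the 6 with the largest increase and the 6 with the largest decrease among regions in the upper 50% of mean signal. That rule picked mostly regions of very high pile-up for 3 marks. A further rule was therefore chosen after the values were seen. It takes the 6 regions per direction that have an island in the higher stage only and lie outside high pile-up regions and dense islands. High pile-up means at least 0.5 reads per bp in either stage, and a dense island has a score of at least 0.1 per bp. Changes of a pair of marks at the same region were set beside the number expected from each mark's share of directions among the regions in both tables. Part of an excess may come from the inputs, which the marks of a stage can share, apart from the separate neonatal input for H3K4me3.

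The alternatives were the MACS lists, the upper 50% of islands by score, equal numbers of top islands, overlap of at least 50% of an island, islands under 3 kb apart merged, autosomes only, a threshold of 4-fold, folds centred on their median, and regions of high mean signal. A threshold of 2-fold, regions with an island in the higher stage, regions above 1 read in both stages, and the removal of high pile-up regions and dense islands were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.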

Results

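Maps of H3K4me3, H3K79me2, H3K27me3 and H3K9me3 were compared between cardiomyocytes of 1-day-old mice and left ventricular cardiomyocytes of 2-month-old mice. H3K4me3 marks promoters, H3K79me2 lies along the first part of transcribed genes, H3K27me3 is the Polycomb mark, and H3K9me3 is a mark of heterochromatin. Each mark was profiled in 1 library per stage, so no difference between the stages has a replicate check. The authors' SICER islands served as the list of enriched regions, and read values came from the 4 tables of stage comparisons. Island numbers ranged from 8059 for neonatal H3K9me3 to 60601 for adult H3K79me2.

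**Figure D1:**
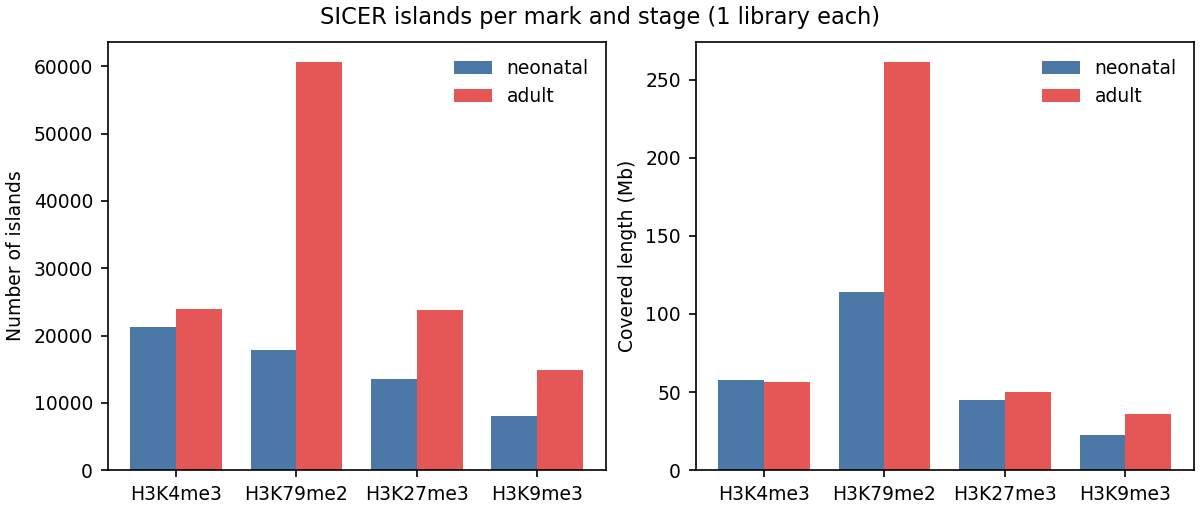
Bars give the number of SICER islands (left) and their covered length in Mb (right) for each mark, in neonatal and adult cardiomyocytes, with 1 library per bar and no error bars. H3K79me2 stood at 17899 neonatal and 60601 adult islands, and H3K4me3 covered 57.5 and 56.4 Mb.

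H3K4me3 SICER islands covered 57.5 Mb in neonatal and 56.4 Mb in adult cells, whereas the MACS regions covered 13.97 and 0.933 Mb, a ratio of 0.0668. There were 21312 neonatal islands with a median width of 2400 bp and 23957 adult islands with a median of 2000 bp. Of the neonatal islands, 64.0% (95% interval 63.4 to 64.7) overlapped an adult island, against 4.75% at random places. Of the adult islands, 56.8% (56.2 to 57.5) overlapped a neonatal one, against 4.25%. Neonatal islands with an adult partner were wider than those without, with medians of 2600 and 2200 bp, and the adult islands covered a median of 77.8% of their length. The MACS lists gave the opposite order, with 12453 neonatal and 5611 adult regions, and with them 26.3% of neonatal regions overlapped an adult one. Their median width was 993 bp in neonatal and 146 bp in adult cells.

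In the authors' deposited table, 5658 H3K4me3 regions were higher in adult and 4736 were higher in neonatal cardiomyocytes. Regions higher in the adult were wider, with a median of 11200 bp against 5894.5 bp. Among regions with an H3K4me3 island in the stage with more reads, the order turned, and 3415 were higher in the adult and 4129 lower. Changes of at least 4-fold numbered 3457 higher and 741 lower, but 2726 of the higher ones stood at the floor of 1 read in the neonatal library. Above the floor at both stages 2932 regions were higher and 4501 lower, and at 4-fold 731 and 506. This filter left out 2726 higher and 235 lower regions, all past 4-fold, so its turn is partly built in.

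The H3K4me3 region with the largest increase, chr4:119246400-119259799, went from 1 read to 1207, at least 128-fold, but its adult island had a score of only 14. The next regions included chr8:34891400-35042999, at least 82.5-fold higher in the adult, and chr14:26269800-26390399, at least 57.4-fold higher. Both had H3K4me3 islands at both stages, although the table gave 1 neonatal read for each. At chr10:7227200-7237799 reads rose from 4 to 2404, 357-fold (interval 139 to 1311), at a dense adult island that adult H3K9me3 shared. At chr17:6471800-6479599 reads went from 73 to 4, 30.7-fold lower (11.5 to 116), and neonatal islands of both H3K4me3 and H3K79me2 had no adult counterpart. At chr10:22529600-22542799 reads went from 143 to 11, 21.9-fold lower (11.9 to 44.8). This region lost its H3K4me3 island, kept an H3K27me3 island and had an H3K9me3 island in the adult only. At chr17:27438400-27474799 reads went from 109 to 3, 61.2-fold lower (20.4 to 301), with H3K4me3 islands at both stages.

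H3K79me2 islands covered 114 Mb in neonatal and 261 Mb in adult cardiomyocytes, 2.29 times as much. Their number was 17899 in neonatal and 60601 in adult cells, and their median width 4400 and 3200 bp. The normalisation factors of 1.41 for the neonatal and 0.707 for the adult library scaled adult reads down against neonatal ones. Island number and length can rise with depth, and its part in the longer adult list was not tested. Factors were also lower in the adult for H3K4me3 and H3K27me3, but not for H3K9me3. Of the neonatal islands 88.5% (88.0 to 89.0) overlapped an adult island against 18.7% at random, but with MACS lists the overlap was 0.833%. In the other direction 33.6% (33.2 to 33.9) of adult islands overlapped a neonatal one, against 6.98%. The widest adult island, 84200 bp at chr4:138763800-138847999, was covered to 93.3% by neonatal islands, and the next, at chr6:31011600-31083799 and chr5:120580000-120651599, to 5.26% and 3.35%. The ratio of covered length was 1.30 with equal numbers of top islands. The MACS lists turned the order, with 13210 neonatal and 2985 adult regions and a ratio of covered length of 0.174. Those regions had median widths of only 123 and 102 bp, so their low overlap need not mean that the enriched stretches differ.

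According to the authors' deposited table, H3K79me2 was higher in the adult at 6820 regions and lower at 5821. With an island required in the stage with more reads, 4647 were higher and 5297 lower, and above the floor of 1 read at both stages, which left out 3962 higher and 255 lower regions, 2858 were higher and 5566 lower. Changes of at least 4-fold numbered 4811 up and 635 down, and 849 and 380 above the floor at both stages. The neonatal and adult libraries of this mark also stood apart in their dense islands, of which 3.13% of 32 neonatal ones were found in the adult list.

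Gains of H3K79me2 at named regions were wide, apart from the largest, at the high pile-up region chr10:104053800-104055399. Reads rose from 1 to 1285 at chr5:120580000-120651599, at least 115-fold, and from 1 to 1097 at chr3:122121400-122205999, at least 98.3-fold. Adult islands were present without a neonatal H3K79me2 island at chr1:93859400-93904199, at least 74.8-fold higher, and at chr8:72087800-72109599, at least 61.8-fold higher. Under the rule added after the values were seen, chr15:84650600-84689999 was at least 47.1-fold and chr7:150598200-150658399 at least 46.0-fold higher. Neonatal H3K27me3 islands lay in both of these regions, and the H3K27me3 table values were also higher in the adult there, by log2 differences of 1.54 and 6.37 in the authors' deposited table. Losses under the same added rule included a pair of neighbouring regions on chromosome 17. Reads fell from 361 to 1 at chr17:5839600-5860799, at least 129-fold, and from 84 to 1 at chr17:5873600-5879599, at least 29.3-fold. At chr2:78744200-78751599 reads went from 86 to 16, 10.7-fold lower (6.25 to 19.6). The 6 largest decreases under the fixed rule were all high pile-up regions, led by chr2:98502200-98507599 with 226727 neonatal reads and 1 adult read.

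H3K27me3 islands were more numerous and narrower in the adult, with 13552 islands of a median 2800 bp in neonatal and 23721 of a median 1800 bp in adult cells. They covered 44.96 and 50.2 Mb. Fewer islands were shared than for H3K4me3, with 43.4% (42.5 to 44.2) of neonatal islands overlapping an adult one against 5.13% at random. Of the adult islands 28.5% (27.9 to 29.1) overlapped a neonatal one, against 3.08%. The widest neonatal island, 57800 bp at chr11:96111400-96169199, was covered to 89.6% by adult islands. The MACS lists held 2450 neonatal and 987 adult regions, and with equal numbers of top SICER islands the adult covered length was 0.840 times the neonatal one.

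H3K27me3 was higher in the adult at 3819 regions and lower at 1450 in the authors' deposited table, so that 72.5% (71.3 to 73.7) were higher. Centring the folds on their median, which makes the split near even by construction, gave 2587 higher and 2485 lower. Regions with an island in the stage with more reads numbered 1651 higher and 1166 lower, and regions above 1 read at both stages 695 higher and 1166 lower. The filter on reads left out 3124 higher and 284 lower regions, so the turn of the majority under it is largely built in. In the neonatal library 58.9% of the reads in this table came from chr2:98502200-98507599, which had 291705 neonatal reads and 1 adult read. In the adult library 13.4% came from chr10:104053800-104055399, which had 1 neonatal read and 89803 adult reads. These regions of very high pile-up differed between the libraries in a way that also split the H3K79me2 and H3K9me3 libraries by stage. The adult side of this split was weak for H3K79me2. High pile-up regions held 0.454% of its adult reads, against 63.6% for adult H3K27me3 and 61.4% for adult H3K9me3. For these 3 marks the split and the stage cannot be told apart.

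All 12 regions picked by the fixed rule for H3K27me3 were of that kind. Under the rule added after the values were seen, H3K27me3 was lost at chr6:47596600-47601790, where reads went from 123 to 1, at least 34.5-fold lower, and where H3K9me3 went from 93 to 1. Reads fell from 47 to 1 at chr9:51568600-51577799, at least 12.8-fold, and from 46 to 1 at chr7:52952800-52957389, at least 12.5-fold. They fell from 40 to 1 at chr12:112675600-112699999, at least 10.8-fold, and from 38 to 1 at chr15:79837000-79847399, at least 10.2-fold. Each of these last 4 regions had H3K4me3 islands at both stages and an H3K79me2 island in the adult. The other 2 of the 6 losses did not. The region on chromosome 6 had no H3K79me2 island. At chr13:19948200-19948599, where reads went from 167 to 2, 133-fold lower (36.2 to 1107), neither mark had an island at either stage. Such islands were not particular to the named losses. Of all losses with a neonatal H3K27me3 island outside high pile-up and dense regions, 521 had H3K4me3 islands at both stages. A further 167 had them in neonatal only, 133 in adult only and 325 at neither stage. H3K79me2 islands lay at 309 in the adult only, at 50 at both stages, at 3 in neonatal only and at 784 at neither stage. Gains included chr11:35728600-35795199, at least 30.1-fold, chr11:106908000-106920199, at least 28.0-fold, and chr6:49131871-49170599, at least 17.1-fold. H3K79me2 changed at these 3 regions by log2 differences of 6.39, 3.96 and -2.20 in the authors' deposited table. H3K4me3 changed there by 6.71, 7.49 and -0.521, and H3K9me3 by 1.33, 1.84 and 1.24. The rise at the 2 regions on chromosome 11 was thus not particular to H3K27me3. At chr11:106908000-106920199 no H3K4me3 island lay at either stage.

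H3K9me3 islands covered 22.6 Mb in neonatal and 36.1 Mb in adult cells, in 8059 and 14921 islands with median widths of 2600 and 2200 bp. Among the SICER lists this mark shared the fewest places between the stages. Of neonatal islands 17.3% (16.5 to 18.2) overlapped an adult island, against 3.11% at random, and of adult islands 9.51% (9.05 to 9.99) overlapped a neonatal one, against 1.70%. An island of 61200 bp at chr7:66776600-66837799, the widest of the adult list, had no neonatal H3K9me3 island within it. Wide H3K4me3 islands lay there at both stages, at chr7:66789400-66833999 in neonatal and chr7:66773600-66817399 in adult cells. The 2 H3K9me3 libraries also lie on different sides of the split by high pile-up regions, so a gain with age cannot be told apart from it. The MACS lists held 484 neonatal and 928 adult regions. With them 4.96% of neonatal regions overlapped an adult one, more than for H3K79me2 (0.833%) and H3K27me3 (0.367%).

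The authors' deposited table listed 4786 H3K9me3 regions as higher in the adult and 4900 as lower. Most lay outside islands, since 7351 of the regions had no H3K9me3 island at either stage. Where the stage with more reads had an island, 1395 were higher in the adult and 804 lower, 63.4% higher (61.4 to 65.4). That requirement can favour the stage with the longer list, and the adult list held 1.85 times as many islands, so no direction was drawn from it. In the neonatal library 58.3% of the reads in this table came from chr2:98502200-98507599, with 692787 neonatal reads and 2 adult reads.

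Under the added rule, H3K9me3 gains clustered on chromosome 4, which held 4 of the 6 largest. These were chr4:146750200-146763199, at least 52.4-fold higher, chr4:146545800-146552999, at least 39.996-fold, chr4:146554188-146557199, at least 34.7-fold, and chr4:146560200-146566799, 206-fold (56.7 to 1708) from 2 reads to 375. All 4 had H3K4me3 islands at both stages, but no neonatal island of H3K79me2, H3K27me3 or H3K9me3. The neonatal libraries of these 3 marks also stand apart by their high pile-up regions. These gains can therefore not be told apart from that split. The largest loss was at chr2:27350400-27358399, where 400 neonatal reads faced 1 adult read, at least 64.9-fold lower, and where the adult had no island of any of the 4 marks. At chr5:105351800-105357799 reads went from 211 to 1, at least 34.1-fold lower. The 12 regions under the fixed rule were all of high pile-up.

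**Figure D2:**
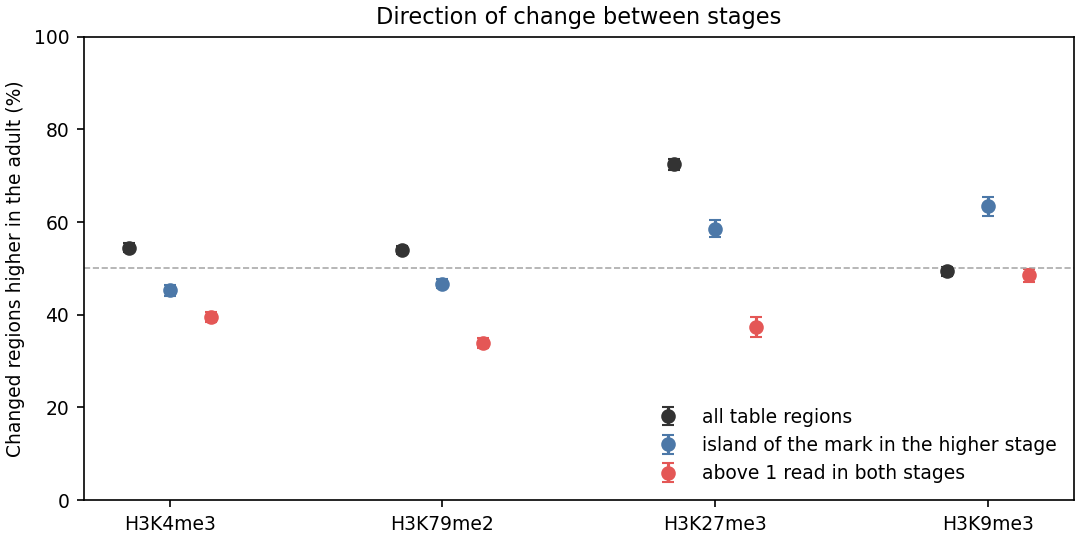
Points give the percent of changed regions that were higher in the adult for each mark, over all table regions, regions with an island of the mark in the higher stage, and regions above 1 read in both stages; bars are 95% Wilson intervals and the dashed line marks equal shares. H3K27me3 went from 72.5% over all regions to 37.3% above 1 read in both stages, a filter that left out 3124 higher and 284 lower regions, and H3K9me3 from 49.4% over all regions to 63.4% with an island in the higher stage, a requirement that can favour the longer adult list.

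**Figure D3:**
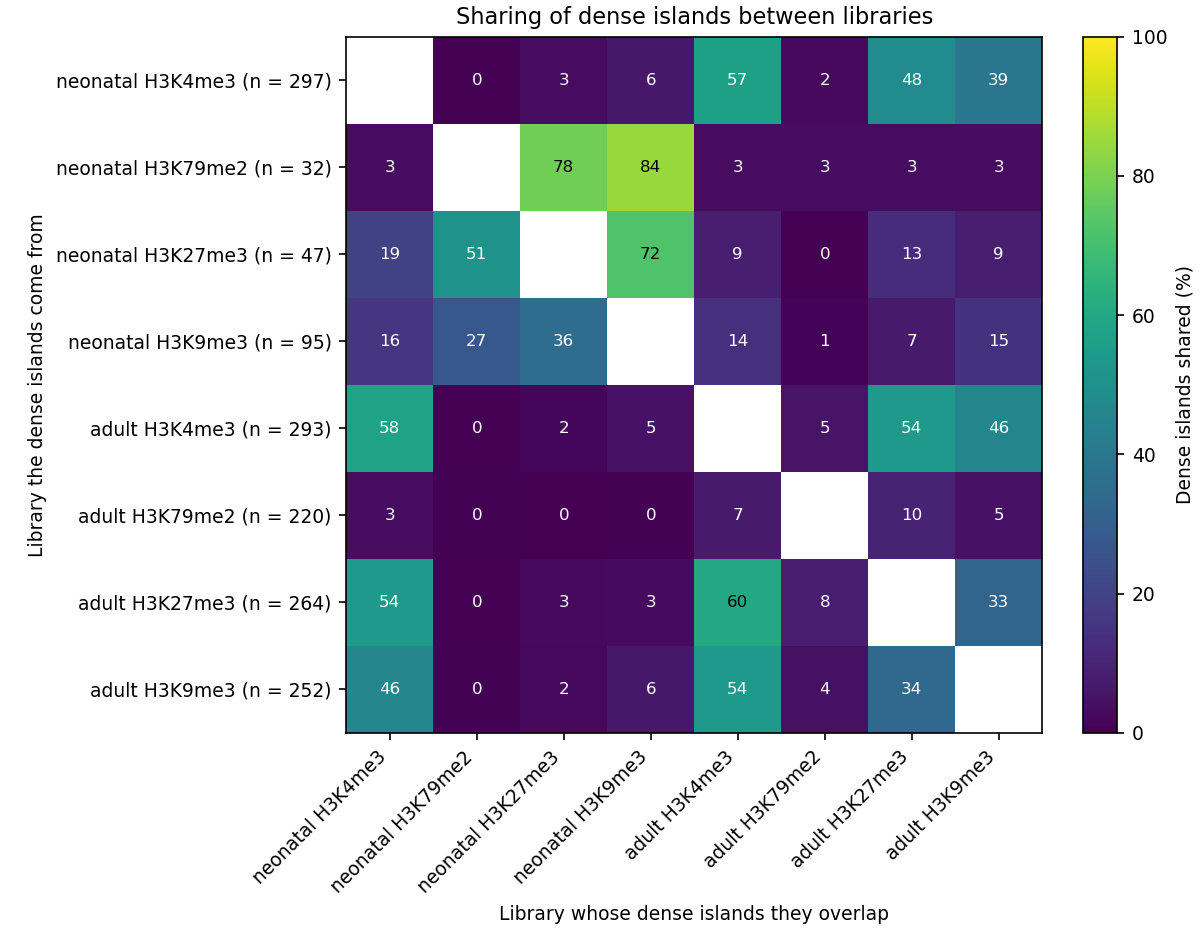
Colours and numbers give the percent of the dense islands of one library (vertical axis, with their number) that overlap a dense island of another library (horizontal axis); the diagonal is empty. Dense neonatal H3K4me3 islands were shared with adult H3K27me3 (48.1%) and less with neonatal H3K27me3 (3.37%), whose list held only 47 dense islands against 264 in the adult one.

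H3K4me3 islands lay together with H3K79me2 and with H3K27me3 islands more often than at random places at both stages. They overlapped H3K79me2 in 36.2% (35.5 to 36.8) of neonatal and 54.3% (53.6 to 54.9) of adult cases, against 6.14% and 15.1% at random. The overlap with H3K27me3 was 13.0% (12.6 to 13.5) in neonatal and 16.8% (16.3 to 17.3) in adult cells, against 3.18% and 4.21%. H3K27me3 and H3K9me3 islands also met often, with 16.7% of H3K27me3 islands overlapping H3K9me3 at either stage against 2.09% and 2.68%. H3K79me2 met H3K27me3 less often than at random places. In neonatal cells 3.25% (2.97 to 3.57) of H3K27me3 islands overlapped H3K79me2 against 6.69%, and in adult cells 12.9% (12.5 to 13.4) against 14.9%. H3K9me3 islands overlapped H3K79me2 in 7.18% (6.64 to 7.77) of neonatal cases against 6.29%, and in 12.2% (11.7 to 12.8) of adult cases against 14.7%. With MACS lists the share of H3K4me3 regions that overlapped H3K79me2 fell to 11.6% in neonatal and 1.12% in adult cells.

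Bivalent islands, H3K4me3 islands that overlap H3K27me3, numbered 2770 in neonatal cells. In the adult, 36.5% (34.8 to 38.3) of them overlapped both marks, 31.5% (29.8 to 33.3) H3K27me3 only, 17.5% (16.1 to 18.97) H3K4me3 only, and 14.4% (13.2 to 15.8) neither. Of the 1012 that overlapped both marks, 29.4% overlapped H3K9me3 in neonatal and 37.5% in adult cells. These shares were 25.2% and 31.2% for H3K27me3 only, 12.0% and 9.90% for H3K4me3 only, and 16.5% and 9.75% for neither. Among all H3K4me3 islands of each stage, 5.61% of neonatal and 14.6% of adult ones overlapped H3K9me3. Islands with H3K79me2 and no H3K27me3 were the most stable class, since 86.5% (85.7 to 87.2) of 7512 overlapped adult H3K4me3 without H3K27me3. Islands of H3K4me3 alone overlapped neither mark in the adult most often among these 3 classes, in 43.3% (42.4 to 44.3) of 10587. A further 6.28% (5.83 to 6.76) of them overlapped H3K27me3 only. Loss of H3K4me3 itself takes in both shares, which for bivalent islands were 14.4% and 31.5%. Islands of H3K4me3 alone and bivalent islands thus differed less in this loss than in the share with neither mark. Outside these classes, islands with H3K9me3 as the only other mark overlapped neither in 46.5% (41.9 to 51.2) of 443. Looking back from the adult, 24.5% (23.2 to 25.9) of 4021 adult bivalent islands overlapped both marks in neonatal cells, and 35.8% (34.3 to 37.3) neither. MACS lists left 57 neonatal bivalent regions, of which 91.2% overlapped neither mark in the adult. The MACS regions of H3K27me3 had median widths of only 113 bp in neonatal and 91 bp in adult cells. The stage comparison of H3K27me3 also sets libraries with different high pile-up regions against each other.

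**Figure D4:**
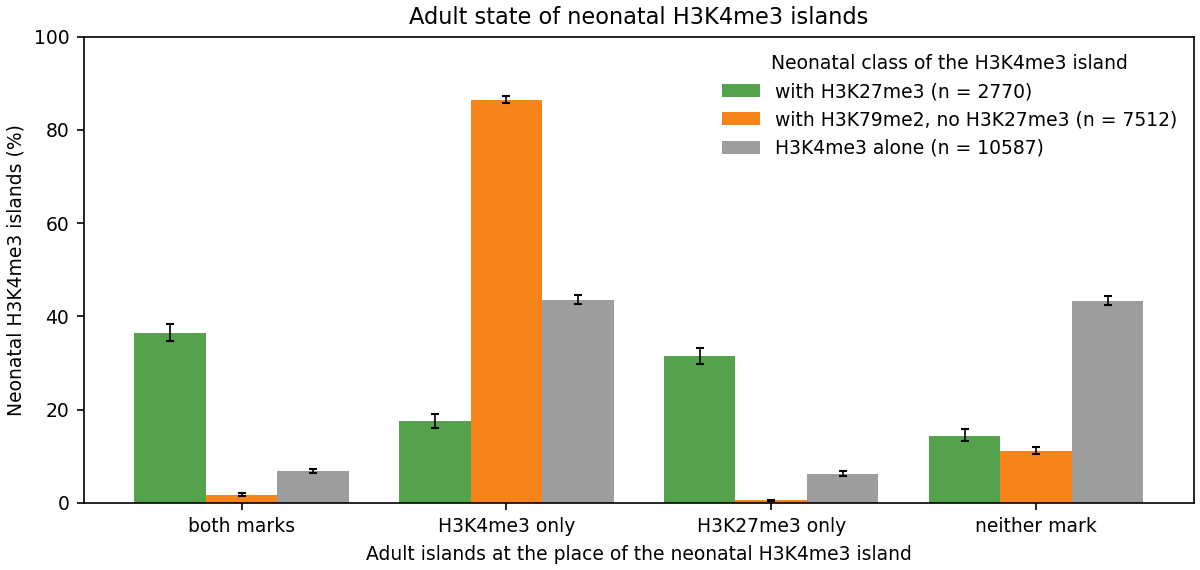
Bars give the percent of neonatal H3K4me3 islands of 3 classes that overlapped adult islands of both marks, H3K4me3 only, H3K27me3 only or neither, with 95% Wilson intervals. Of the class with H3K27me3, 36.5% overlapped both marks, and of the class with H3K79me2 and no H3K27me3, 86.5% overlapped H3K4me3 only.

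H3K27me3 and H3K9me3 exceeded the expected share of changes in the same direction by more than any other pair of marks. Of 3099 regions in both tables, 78.1% (76.6 to 79.5) changed in the same direction, against 56.5% expected from the directions of each mark. With islands in the higher stage for both, 469 regions were higher and 248 lower for both marks, 82.7% against 53.2% expected. Without high pile-up regions the share was 77.4% against 56.1%. An excess was also present at the 1063 regions with an island of neither mark, 75.6% (73.0 to 78.1) against 59.6%, so it was not limited to places with islands. Directions of H3K4me3 and H3K79me2 matched in 56.7% (55.5 to 57.8) of 7026 regions against 50.8% expected, those of H3K4me3 and H3K27me3 in 66.2% (64.5 to 67.9) of 3092 against 56.0%. H3K79me2 and H3K27me3 matched less often than expected, in 57.5% (55.8 to 59.1) of 3390 regions against 61.3%. With islands in the higher stage for both, H3K79me2 rose and H3K27me3 fell at 328 regions (283.8 expected), and the reverse held at 147 (102.8 expected). H3K9me3 matched H3K79me2 in 60.6% (59.4 to 61.8) of 6490 regions against 49.8%, and H3K4me3 in 55.4% (54.1 to 56.8) of 5437 against 50.1%. With islands in the higher stage for both, H3K4me3 and H3K9me3 matched in 53.6% (50.4 to 56.8) against 51.96% expected, within the counting interval. H3K79me2 and H3K27me3 matched more often than expected among changes of at least 4-fold in both marks, 86.2% against 79.9%, and at the 254 regions with an island of neither mark, 86.2% (81.4 to 89.9) against 72.6%. The inputs may be shared between marks of a stage, so part of an excess can come from them. The labels name a separate neonatal input for H3K4me3, so for pairs with H3K4me3 this may hold for the adult stage only. The H3K27me3 and H3K9me3 libraries are also split by stage in the same way. Of 47 dense neonatal H3K27me3 islands, 72.3% were shared with neonatal and 8.51% with adult H3K9me3. A difference between libraries could move both marks the same way, so the excess of this pair cannot be told apart from it.

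The tables against mES cells, which are pluripotent, set each stage against an undifferentiated state. By the authors' deposited table for adult H3K79me2, 7787 regions were higher than in mES cells and 6077 lower, and at 4-fold 6166 and 2093. For neonatal H3K79me2 the authors' deposited table gave 5230 higher and 5780 lower, but 3285 higher and 2674 lower at 4-fold. H3K4me3 was evenly split in the authors' deposited table for either stage, with 5787 higher and 5889 lower in neonatal and 6390 and 6483 in adult cells. At 4-fold the authors' deposited table had 2019 H3K4me3 regions higher and 2924 lower in neonatal cells, and 2545 and 982 in adult cells. H3K27me3 counts in the authors' deposited table were 3046 higher and 3166 lower in neonatal and 5184 and 5041 in adult cells. At 4-fold the authors' deposited table held 1775 higher and 3024 lower H3K27me3 regions in neonatal and 2898 and 4182 in adult cells. Of the regions lower than in mES cells in the authors' deposited table, 86.7% in neonatal and 92.4% in adult cells had no H3K27me3 island. For H3K9me3 the authors' deposited table gave 4626 higher and 4570 lower in neonatal and 4970 and 4737 in adult cells. At 4-fold the authors' deposited table gave 2218 higher and 3311 lower in neonatal and 2901 and 3460 in adult cells, where the majority turned. The neonatal split of all regions in the authors' deposited table was even within its interval, 50.3% higher (49.3 to 51.3). At chr10:22529600-22542799 the authors' deposited table set H3K4me3 in mES cells below neonatal cells by a log2 difference of -3.02 and above adult cells by 1.55. The mES libraries came from other studies, so study and cell type differ together.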

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

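The tests of shared dense islands in this part were chosen only after the pile-ups had been seen. MACS regions on contigs outside chromosomes 1 to 19, X and Y, which no comparison used, were above 0 in 5 libraries and 0 in the neonatal H3K79me2, H3K27me3 and H3K9me3 libraries. There were 63 in neonatal H3K4me3, 52 in adult H3K4me3, 8 in adult H3K79me2, 10 in adult H3K27me3 and 73 in adult H3K9me3.

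The same libraries also differed in their dense islands. Of the 297 dense islands of neonatal H3K4me3, 3.37% (1.84 to 6.09) lay at those of neonatal H3K27me3. At those of adult H3K27me3 lay 48.1% (42.5 to 53.8). This comparison cannot decide on developmental stage as the cause, because the H3K27me3 lists held 47 neonatal and 264 adult dense islands. The H3K4me3 lists were of like size, 297 and 293. Of the 264 dense adult H3K27me3 islands, 54.2% (48.1 to 60.1) lay at those of neonatal H3K4me3. At those of adult H3K4me3 lay 60.2% (54.2 to 65.9), with overlapping intervals. A processing batch that split the libraries, such as another handling of repeated sequence, may account for both patterns and stays open, although adult H3K79me2 shared few of its dense islands with any library. For H3K79me2, H3K27me3 and H3K9me3 the stages lie on different sides of this split, so a difference between stages cannot be told apart from it, and age stays open as untested.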

How the results depend on the processing

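The requirement of an island in the higher stage, the floor of 1 read, the 2-fold threshold and the removal of high pile-up regions and dense islands were chosen as alternatives only after seeing the data. A 2-fold rule had been planned only for tables not already cut at a threshold of the authors. Of the alternatives for results that answer a comparison, 89 left the value in place, 75 moved it and 16 reversed it. A share was taken as moved when it left its counting interval, however small the step, and a count or ratio when it changed by more than 1.5 times. For single values among many, 48 left it and 40 moved it. The cause of the changes below was not tested unless given. No fold threshold gave the counts already reported, and the upper 50% by score fixes the ratio of island numbers, so only covered length was compared there. Gene lists and the choice of a region per gene were not run, because an annotation of mm9 was not used here. No paired analysis was possible because each group holds 1 library. Folds of regions at the floor of 1 read were given as bounds for reads left after control subtraction, and whether depth or the subtraction put them at the floor was not tested.

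MACS regions were narrower than SICER islands. Their neonatal and adult median widths were 993 and 146 bp for H3K4me3 and 123 and 102 bp for H3K79me2. They were 113 and 91 bp for H3K27me3 and 111 and 79 bp for H3K9me3. A low overlap of such narrow regions need not mean that the enriched stretches differ. With MACS lists the adult over neonatal ratio of region numbers reversed to 0.451 for H3K4me3, 0.226 for H3K79me2 and 0.403 for H3K27me3. The ratio of covered length became 0.0668 for H3K4me3 and reversed to 0.174 for H3K79me2 and 0.477 for H3K27me3. With equal numbers of top islands covered length was 1.30 for H3K79me2 and reversed to 0.840 for H3K27me3. Overlap of neonatal with adult MACS regions was 26.3% for H3K4me3, 0.833% for H3K79me2, 0.367% for H3K27me3 and 4.96% for H3K9me3, and of adult with neonatal regions 72.0%, 3.58%, 0.912% and 2.48%. MACS regions of H3K4me3 overlapped H3K79me2 in 11.6% of neonatal and 1.12% of adult cases, and H3K27me3 in 0.458% and 1.14%. The 57 bivalent MACS regions overlapped both marks in 3.51%, H3K4me3 only in 5.26%, H3K27me3 only in 0% and neither in 91.2%.

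Requiring 50% of an island to be covered gave an overlap of neonatal islands of 53.2% for H3K4me3, 74.4% for H3K79me2, 26.8% for H3K27me3 and 11.4% for H3K9me3, and of adult islands 51.1%, 26.0%, 22.9% and 6.21%, lower by construction. H3K4me3 islands then overlapped H3K79me2 in 28.9% of neonatal and 44.6% of adult cases, and H3K27me3 in 9.99% and 12.0%. Neonatal bivalent islands then overlapped both marks in 30.6%, H3K4me3 only in 21.3%, H3K27me3 only in 28.2% and neither in 19.9%. In the upper 50% by score, overlap of neonatal islands was 71.3% for H3K4me3, 84.8% for H3K79me2 and 47.7% for H3K27me3, and of adult islands 63.6%, 32.8% and 31.8%.

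At 4-fold, 3457 H3K4me3 regions were higher in the adult, and 741 H3K4me3, 635 H3K79me2, 447 H3K27me3 and 3227 H3K9me3 regions were lower. At 2-fold, 2682 H3K4me3, 3282 H3K79me2 and 931 H3K27me3 regions were lower. Among regions of the upper 50% of mean signal the majority reversed for H3K4me3, with 2072 higher and 3120 lower, and for H3K79me2, with 1935 higher. H3K27me3 had 1464 higher there, and H3K9me3 2422 higher and 2418 lower. Centred folds, near even by construction, gave 2485 lower for H3K27me3. With an island in the higher stage the majority reversed for H3K4me3, with 3415 higher, and for H3K79me2, with 4647 higher. H3K27me3 then had 1651 higher, and H3K9me3 1395 higher and 804 lower. Above 1 read at both stages, a filter that leaves out large changes by construction, the majority reversed for H3K4me3, H3K79me2 and H3K27me3, with 2932, 2858 and 695 higher, and H3K9me3 had 2426 higher and 2572 lower.

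Shares of the same direction at 4-fold were 85.2% (75.8% expected) for H3K4me3 with H3K79me2 and 88.5% (80.5%) for H3K4me3 with H3K27me3. They were 60.2% (52.3%) for H3K4me3 with H3K9me3, 69.9% (57.6%) for H3K79me2 with H3K9me3 and 86.8% (66.4%) for H3K27me3 with H3K9me3. The expected shares rose at 4-fold as well, so a higher share alone is no closer match. For H3K79me2 with H3K27me3 the share, 86.2%, reversed to above the expected one. With islands in the higher stage for both marks the share was 60.03% (49.7% expected) for H3K4me3 with H3K27me3. It was 53.6% (interval 50.4 to 56.8) for H3K4me3 with H3K9me3, which holds the 51.96% expected. For H3K79me2 it was 46.5% (56.5% expected) with H3K27me3 and 57.3% (48.0%) with H3K9me3. H3K27me3 with H3K9me3 stood at 82.7% (53.2%). Against mES cells, the share higher at 4-fold in the authors' deposited table was 40.8% for neonatal and 72.2% for adult H3K4me3, 74.7% for adult H3K79me2, 37.0% and 40.9% for neonatal and adult H3K27me3 and 40.1% for neonatal H3K9me3. It reversed to 55.1% for neonatal H3K79me2 and 45.6% for adult H3K9me3 in the authors' deposited table.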

Other observations

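The sorting of changed regions by islands of another mark and the tests of region width and of the X chromosome in this part were chosen only after the results had been seen. Neonatal bivalent islands overlapped H3K79me2 more often in the adult in all 4 classes of adult state. Of the 485 islands that overlapped only H3K4me3 in the adult, 20.6% (17.3 to 24.4) overlapped H3K79me2 in neonatal and 53.4% (49.0 to 57.8) in adult cells. The 1012 islands that overlapped both marks in the adult went from 5.73% (4.46 to 7.34) to 26.7% (24.05 to 29.5), and the 873 that overlapped only H3K27me3 from 1.37% (0.788 to 2.39) to 12.0% (10.03 to 14.4). The 400 that overlapped neither went from 6.5% (4.47 to 9.35) to 29% (24.8 to 33.6), and the class with only H3K4me3 had the smallest relative rise. Adult H3K79me2 islands were 3.39 times as many as neonatal ones, so a rise in each class was not specific to it, and the difference between the classes was not tested.

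The direction of changed regions was sorted by islands of another mark, counted where the higher stage had an island and outside high pile-up and dense regions. H3K79me2 was higher in the adult at 84.7% (81.0 to 87.8) of 431 regions with a neonatal-only H3K27me3 island and at 92.4% (90.1 to 94.2) of 671 with H3K27me3 islands at both stages, at 62.2% (57.7 to 66.5) of 471 with an adult-only one, but at 40.1% (39.1 to 41.2) of 8321 with none. This was not particular to H3K27me3, since by H3K9me3 islands the shares were 84.8% with both stages, 71.5% adult-only, 66.0% neonatal-only and 43.0% with none. H3K4me3 was higher at 14.4% (10.3 to 19.7) of 215 regions with a neonatal-only H3K79me2 island and at 54.4% (52.9 to 56.0) of 3915 with islands at both stages, and at 43.1% of 1349 with an adult-only island and 29.2% of 1932 with none. By H3K27me3 state the H3K4me3 share ran only from 42.6% to 54.1%. H3K9me3 was higher at 90.03% (86.5 to 92.7) of 361 regions with an adult-only H3K27me3 island and at 31.0% (23.5 to 39.5) of 126 with a neonatal-only one, against 53.5% (49.7 to 57.2) of 692 with islands at both stages and 64.0% (60.8 to 67.1) of 900 with none. The requirement of an island in the higher stage itself moved these shares. Without it they ran from 52.5% to 58.2% for H3K4me3 by H3K27me3 state, and turned to 54.6% (52.3 to 56.8) of 1858 regions for H3K4me3 with an adult-only H3K79me2 island, and to 46.1% (44.9 to 47.3) of 6925 for H3K9me3 with no H3K27me3 island. These differences were not tested, and for H3K79me2 and H3K9me3 the stages also differ in the libraries' dense islands.

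H3K4me3 table values were higher in the adult mostly at wide regions, from 31.2% of the narrowest of 5 equal groups to 81.3% of the widest. Wider adult islands as the whole cause are argued against by the 1265 regions of the widest group with islands at both stages and more than 1 read in both, where the median adult over neonatal ratio was 1 (0.941 to 1) for island length and 1.76 (1.69 to 1.84) for normalised reads. Regions without an island of the mark at either stage rose with width from 55.3% (51.0 to 59.4) to 97.9% (95.6 to 99.0), as they did for H3K79me2 (73.3% to 96.2%) and H3K27me3 (67.2% to 99.8%) but not for H3K9me3 (49.8% to 40.6%). Over all regions the share fell with width for H3K79me2 (68.2% to 40.5%) and H3K9me3 (59.9% to 40.4%) and rose for H3K27me3 (69.1% to 76.5%). A candidate explanation for a rise with width is the subtraction of control reads over the whole region. It stays open because the sources used here do not give which input served which table. More reads within islands of the same length, and age, stay open as untested.

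Islands on the X chromosome covered less of it in the adult. For H3K4me3 they fell from 1537.6 kb to 680.2 kb, and the X ratio was 0.444 (bootstrap interval 0.377 to 0.525) of the autosome ratio. A change of H3K4me3 alone as the whole cause is argued against by H3K79me2, H3K27me3 and H3K9me3, whose ratios were 0.338, 0.420 and 0.535 with no upper bound above 0.808, and the split of the libraries by dense islands as the whole cause by the H3K4me3 pair, whose dense islands are shared, but both acting together stay open. Fewer X copies among the adult animals may account for the fall, and Y leaves this open, since islands there rose from 2 to 16.4 kb for H3K4me3 but fell from 18.4 to 0 kb for H3K79me2, from 50 to 1 kb for H3K27me3 and from 230.6 to 57.2 kb for H3K9me3. The labels used here give no sex of the animals, and a change of the X chromosome with age stays open as untested.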
